A study of Mus musculus with 18 samples.

How the data were processed

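RNA from the whole blood of 18 mice was measured on Agilent 1-colour mouse arrays, with 1 array per mouse. Per the labels, the mice were male C57BL/6N animals exposed to a cesium gamma source or sham treated, and blood was drawn by cardiac puncture 6 hours after exposure. RNA was purified with PAXgene or RiboPure kits, globin RNA was removed, and the RNA was amplified and labelled with Cy3. The labels gave each mouse its dose and kit. The file headers gave the slide and the scan day of each array: the 18 arrays came from 8 slides scanned on 7 days.

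The scanner files hold a processed signal for 43379 spots, controls left out, which stand for 41174 different probes. Per the file headers, this intensity was made by Agilent Feature Extraction 9.5.3.1 with background subtraction and with spatial and multiplicative detrending. The deposited table of the series holds an intensity on a linear scale. Its 18 columns had nearly the same sorted values and a median of 20.7 each, so the columns had been quantile normalized. Its logarithm correlated with that of the processed signal with r from 0.989 to 1.000 over 41174 probes within an array. The steps between the scanner files and this table are not stated. The submitters' processing notes name limma without saying for which step.

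The processed signals were taken to log2, averaged over the spots of a probe and reduced by the 75th percentile of the array's non-control probes. A total of 45 values of a probe on an array were left out because the scanner software had marked the spots as outliers. Probes that the software called well above background on at least 5 of 18 arrays were kept, 22038 in all. Names were updated with a table of RefSeq accessions and symbols: 22951 probes were named through their accession, 9767 through a symbol or an older symbol, 825 kept the name in the file, and 7631 had no gene name. Of the 20243 named genes on the array, 13260 had a probe past the filter, and 4740 of these had more than 1. The probe with the highest mean over the 18 arrays stood for its gene. Probe positions are those of the files, on the mouse build mm7. No genome sequence was at hand to check them, so they serve only to identify the probe.

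A linear model with the dose and the kit as terms was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3, with statmod 1.5.0 and the data.table package, version 1.17.8. Errors given beside log2 fold changes are standard errors of this model, and those beside group means are standard deviations. Tests were 2-sided, p was adjusted by the Benjamini-Hochberg method over the genes tested, and the threshold was an adjusted p of 0.05. Where a probe was well above background on none of the arrays of a group, its fold is given only as a bound. The bound sets the other group's mean signal against the lowest signal called well above background on each array, and no fold is given where it falls under 1.

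The design, the tests of the comparisons, 24 gene lists and the alternatives were fixed before the data were examined, apart from the alternatives and tests named as chosen later. The lists cover p53 targets, DNA repair, G1/S and replication, G2/M and mitosis, apoptosis regulators of the Bcl2 family, interferon response, NF-kB and inflammatory, immediate early, heat shock, glucocorticoid response, NRF2 and oxidative stress, MHC class II, ribosomal protein and mitochondrial respiratory chain genes. The other 10 hold markers of B cells, T cells, NK and cytotoxic cells, mature neutrophils, neutrophil precursors and granules, monocytes, eosinophils with basophils and mast cells, plasma cells, erythroid cells and reticulocytes, and platelets and megakaryocytes. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 24 lists. Members past the threshold were counted after adjustment over all genes and after adjustment over the list alone.

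The genes named were the 10 largest rises and 10 largest falls past the threshold for each dose against 0 Gy, and the 5 of each for 8 Gy against 2 Gy. Added to these were 12 core p53 targets whatever their result, up to 4 members of each list with the smallest p, and the 3 largest differences of each sign between the kits. Sesn1, Bmf, Mmp8 and Padi4 fall outside this rule and were chosen after their values were seen, to complete counts of 5 or fewer.

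A score per array was the mean over a list's measured members of the log2 value minus its mean over the 0 Gy arrays. Scores of 10 lists were compared between doses by exact 2-sided permutation tests over all splits of the arrays, and p was adjusted over the 30 tests. To assign arrays to doses, each array was left out in turn, the 20 genes with the largest moderated F for dose were chosen in the remaining arrays, and the array was given the dose of the nearest group mean, with 100 orders of the dose labels for the permutation test.

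The model was tested on simulated data with changes put into 200 of 13260 genes. It recovered 16, 39, 46 and 50 of 50 genes changed by 2-, 4-, 8- and 16-fold at 2 Gy with 11 false calls, and 24, 39, 47 and 48 of 50 at 8 Gy with 4 false calls. Of 24 random lists of 30 genes, 1 was moved 2-fold at 8 Gy, and camera with the preset correlation called that 1 and 0 of the others. Genes and arrays were drawn independently, with no effect of the slide or the brightness. The simulations therefore cannot show how often false calls arise where genes are correlated or slides differ.

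Alternatives changed 1 choice at a time, except that a setting added later joined the slide as a block with an array left out. For the values these were background correction by normexp with an offset of 50, quantile normalization or the median in place of the 75th percentile, the deposited table in place of the scanner values, and no filter or a filter on all 18 arrays. For the model they were the treatment of several probes and of marked spots, the kit, slide, scan day and replicate number, the variance model, and the arrays in the model. Each array was also left out in turn, and the threshold was set to a fold of at least 2 or an adjusted p under 0.01. Under an alternative, a tested value was read by its direction and its side of the threshold. A count was called unchanged within 1.5 times its main value, and a value with no test when it moved by less than 1 standard deviation between arrays.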

Results

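The series asks which transcripts in blood mark an exposure to radiation. Whole blood of 18 male mice of the inbred C57BL/6N strain was profiled 6 hours after exposure to gamma rays or sham treatment: 7 mice at 0 Gy, 5 at 2 Gy and 6 at 8 Gy, with 1 array each. RNA had been purified with the RiboPure kit in 15 mice (5, 4 and 6 at 0, 2 and 8 Gy) and with the PAXgene kit in 3 (2, 1 and 0). The 75th percentile of the processed signal ranged from 148 to 443 intensity units at 0 Gy, from 49.2 to 198 at 2 Gy and from 61.3 to 247 at 8 Gy. Between 19266 and 24450 probes were well above background at 0 Gy, between 15458 and 19520 at 2 Gy and between 16943 and 22789 at 8 Gy. The number of arrays limits the precision of every value.

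Some arrays stood apart from their group. The array labelled 0 Gy replicate 5 had a p53 target score of 1.13, against -0.32 to -0.11 for the other 6 arrays at 0 Gy, and it was singled out after these values were seen. It stays at 0 Gy as labelled. The counts of genes that passed in the dose comparisons, and some of those within lists, are also given without it. On the first principal component, which held 29.4% of the variance, 0 Gy replicate 4 and 2 Gy replicate 3 lay at -126.4 and -112.0, and their median correlations with the other arrays were 0.831 and 0.844.

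After 8 Gy, targets of the transcription factor p53 were higher in blood and transcripts of B cells were lower than after 0 Gy. Cdkn1a, an inhibitor of cyclin-dependent kinases and a textbook p53 target, rose by 3.41 ± 0.56 on the log2 scale (6 against 7 arrays, adjusted p = 0.00848). It went from a mean of -1.96 ± 1.69 (n = 7) to 1.92 ± 0.54 (n = 6). Its probe lies on chromosome 17 from 27293819 to 27293878. Tnfrsf13c, the receptor through which the survival factor BAFF acts on B cells, fell by 4.50 ± 0.72 (adjusted p = 0.00848, chromosome 15 from 82306190 to 82306249). Il1r2, a decoy receptor for interleukin 1 made by neutrophils, rose by 4.05 ± 0.76 (adjusted p = 0.00906, chromosome 1 from 40362239 to 40362298). Leaving aside the array labelled 0 Gy replicate 5, each of these genes lay outside the range of the other 0 Gy arrays in 6 of 6 arrays at 8 Gy.

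Of 13260 genes tested, 1585 passed the threshold at 8 Gy, 1013 higher and 572 lower, and 757 and 290 of them changed by at least 2-fold. An unadjusted p under 0.05 was reached by 4398 genes, where 663 are expected by chance. Without the array labelled 0 Gy replicate 5, 3022 genes passed, 2054 higher and 968 lower, and 1584 of the 1585 were among them. Of the calls, 63.9% were higher, against 45.9% with quantile normalization, 45.4% with the deposited table and 44.2% with normexp. The count fell to 0 in limma with the slide or the scan day as a block, where 1130 and 2460 genes had an unadjusted p under 0.05. With these blocks the 1585 genes kept their sign, with a median size of 0.87 and 0.98 in place of 1.13 and a median standard error of 0.49 and 0.41 in place of 0.31. The count was also 0 with the log2 brightness of the array as a covariate, added after seeing the data (1854 genes). It was 268 without 0 Gy replicate 1, 320 without replicate 2, 863 without replicate 3, 786 without replicate 4, 1011 without replicate 6 and 850 without replicate 7. It was 950 and 598 without 2 Gy replicates 1 and 5, 2873 without 8 Gy replicate 1, and 616, 557, 374, 453 and 383 without 8 Gy replicates 2 to 6.

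The largest rises at 8 Gy, beside Cdkn1a and Il1r2, were those of Crispld2, which encodes a secreted protein that binds lipopolysaccharide (5.07 ± 0.91, adjusted p = 0.00887), Psrc1, which encodes a spindle protein (4.37 ± 0.70, 0.00848), and Scrg1 (3.47 ± 0.63, 0.00894). 1700007K13Rik (5.19 ± 0.74, adjusted p = 0.00831) and Tnfsf4, the ligand of the T cell costimulatory receptor OX40 (4.26 ± 0.80, 0.00906), also rose. Both were well above background on 1 of 7 arrays at 0 Gy and 6 of 6 at 8 Gy, so the size of their rise rests on 0 Gy values near the background. Celf5, for an RNA-binding protein, was well above background on 0 of 7 arrays at 0 Gy and 5 of 6 at 8 Gy, and was at least 3.74-fold higher (adjusted p = 0.00848). A930001C03Rik was well above background on 0 of 7 and 4 of 6 arrays and was at least 2.62-fold higher (adjusted p = 0.00848). Chrna10, a subunit of nicotinic acetylcholine receptors, rose by 3.53 ± 1.04 (adjusted p = 0.0411) and differed by 4.94 ± 1.18 between the kits. It kept its call in 14 of 33 settings, in which its adjusted p ranged from 0.0181 to 0.606. The 10 largest falls were those of Tnfrsf13c, 6 other genes of B cells, Srpk3, for a protein kinase (-4.37 ± 0.85, adjusted p = 0.0105), Pla2g2d, for a secreted phospholipase (-3.93 ± 0.60, 0.00831), and Bend5 (-3.51 ± 0.52, 0.00831).

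Among the p53 targets, 31 of 44 measured rose at 8 Gy, 1 fell and 12 did not pass, and 34 rose and 1 fell when adjusted over the list alone. Their median was 1.20, a 2.30-fold change. The list had a camera adjusted p of 1.63e-14, and adjusted p = 0.259 with an estimated correlation. The rises included Phlda3, which encodes an inhibitor of the kinase Akt (2.85 ± 0.50, adjusted p = 0.00848), and Ccng1, for cyclin G1 (2.19 ± 0.33, 0.00831). The death receptor gene Fas (1.80 ± 0.33, adjusted p = 0.00906) and Cd80, a costimulatory ligand on antigen-presenting cells (2.32 ± 0.38, 0.00848), rose as well. Aen (1.81 ± 0.29, adjusted p = 0.00848), Zmat3 (1.63 ± 0.29, 0.00848), Trp53inp1 (1.54 ± 0.31, 0.0114) and Mdm2, for the ubiquitin ligase that degrades p53 (1.20 ± 0.29, 0.0216), also rose. Ddb2, which acts in nucleotide excision repair, had a log2 fold change of -0.19 ± 0.28 (adjusted p = 0.661). Eda2r was well above background on 0 arrays and was not tested. Sesn1, for a stress-induced protein of the sestrin family, was the member that fell, by 0.91 ± 0.29 (adjusted p = 0.0497). It kept its call in 10 of 34 settings and was chosen after its values were seen.

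Of 14 measured apoptosis regulators of the Bcl2 family, 4 rose at 8 Gy, 1 fell and 9 did not pass (8 and 1 adjusted over the list alone). The rises were those of the pro-apoptotic genes Bbc3 (2.10 ± 0.40, adjusted p = 0.00923), Bax (1.57 ± 0.32, 0.0134), Pmaip1 (1.49 ± 0.37, 0.0259) and Bcl2l11 (1.13 ± 0.26, 0.0203). Bmf, also pro-apoptotic, fell by 1.08 ± 0.30 (adjusted p = 0.0349) and was chosen after its values were seen. Bbc3, Bax and Pmaip1 are also on the list of p53 targets and were counted there as well. The list's median was 0.63 with a camera adjusted p of 0.0226, and adjusted p = 0.371 with an estimated correlation. DNA repair genes had a median of -0.42, and 0 of 31 rose and 7 fell (1 and 8 adjusted over the list alone). Parp1, which signals DNA strand breaks, fell by 1.48 ± 0.27 (adjusted p = 0.00906). Xrcc6 and Xrcc5, the Ku subunits of DNA end joining, fell by 0.94 ± 0.22 (0.0219) and 0.90 ± 0.22 (0.0233). Fanca, of the Fanconi pathway, fell by 0.86 ± 0.23 (0.0339). Of 29 G1/S and replication genes 3 fell, over all genes and adjusted over the list alone. They were the licensing factor Cdt1 (-0.79 ± 0.19, adjusted p = 0.0234) and the helicase subunits Mcm5 (-0.77 ± 0.23, 0.0421) and Mcm3 (-0.80 ± 0.25, 0.0459), of which Mcm5 and Mcm3 kept their calls in 14 and 11 of 34 settings. The camera adjusted p was 2.79e-04 for DNA repair and 0.00153 for the replication list (median -0.40), and with an estimated correlation adjusted p = 0.352 and 0.371.

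B cell markers fell together at 8 Gy. Of 28 measured, 24 fell, 0 rose and 4 did not pass (24 fell and 1 rose adjusted over the list alone). The median was -2.72, 6.59-fold lower. Beside Tnfrsf13c, Pax5, the transcription factor that holds B cell identity, fell by 3.88 ± 0.92 (adjusted p = 0.0219), and Fcmr, the receptor for IgM, fell by 3.86 ± 0.69 (0.00887). Cd22, an inhibitory receptor of B cells, fell by 3.80 ± 0.69 (0.00901), and Fcer2a, the low-affinity receptor for IgE, fell by 3.65 ± 0.55 (0.00831). Cd79b, a signalling chain of the B cell receptor, fell by 3.58 ± 0.61 (adjusted p = 0.00848, chromosome 11 from 106420507 to 106420566). An immunoglobulin kappa variable segment, with its probe on chromosome 6 from 67701639 to 67701698, fell by 3.65 ± 0.67 (0.00906). Fcrl1 (-2.34 ± 0.39, 0.00848) and Cd72 (-2.26 ± 0.38, 0.00848) also fell. MHC class II genes, which present antigen to T cells, fell in 10 of 10 measured (10 adjusted over the list alone), with a median of -2.06. They included H2-Oa (-3.03 ± 0.54, adjusted p = 0.00887), H2-Ob (-2.86 ± 0.47, 0.00848), H2-Aa (-2.37 ± 0.55, 0.0203) and their transactivator Ciita (-2.82 ± 0.56, 0.0113). By camera the adjusted p was 8.33e-20 for B cell markers and 2.29e-09 for MHC class II genes, and with an estimated correlation adjusted p = 0.259 and 0.301.

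Of 30 T cell markers, 2 fell and 28 did not pass (2 adjusted over the list alone), with a median of -0.17. Ccr7, which guides naive T cells to lymph nodes, fell by 1.51 ± 0.31 (adjusted p = 0.0135), and Cd8b1, a chain of the CD8 co-receptor, fell by 1.31 ± 0.33 (0.0256). The other probe of Cd8b1 had the opposite sign. The list had a camera adjusted p of 0.0394, and adjusted p = 0.706 with an estimated correlation.

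Mature neutrophil markers rose at 8 Gy in 20 of 25 measured, and 5 did not pass (22 rose adjusted over the list alone), with a median of 2.22, a 4.65-fold change. With Il1r2 rose Trem1, a receptor that amplifies myeloid inflammation (2.82 ± 0.49, adjusted p = 0.00848), Mmp9, a gelatinase stored in neutrophil granules (2.31 ± 0.46, 0.0114), and Mcemp1 (2.00 ± 0.40, 0.0113). Of 17 neutrophil precursor and granule genes 5 rose (8 and 1 lower adjusted over the list alone), with a median of 0.49. They were Mmp8, for neutrophil collagenase (3.38 ± 0.85, adjusted p = 0.0262), Lcn2, for the iron-trapping protein lipocalin (3.25 ± 0.70, 0.0152), Cd177 (1.57 ± 0.37, 0.0215), Pglyrp1, a peptidoglycan-binding protein (1.88 ± 0.47, 0.0254), and Padi4, for a histone-modifying enzyme of neutrophils (1.37 ± 0.41, 0.0423). Mmp8 and Padi4 were chosen after their values were seen, and Padi4 kept its call in 11 of 34 settings. These lists had camera adjusted p of 3.21e-12 and 0.0214, and with an estimated correlation adjusted p = 0.305 and 0.371.

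Platelet and megakaryocyte genes had a median of 1.03, and 7 of 25 rose (21 adjusted over the list alone). Among them was Pf4, a platelet chemokine (1.05 ± 0.30, adjusted p = 0.0393). Erythroid and reticulocyte genes had a median of 0.84, and 6 of 40 rose (18 adjusted over the list alone). Among them were the peroxidase gene Prdx2 (1.21 ± 0.29, adjusted p = 0.0221), the transcription factor gene Tal1 (1.17 ± 0.35, 0.0428) and Mkrn1 (1.13 ± 0.34, 0.0428). Over 34 settings Pf4 kept its call in 11 and Tal1 and Mkrn1 in 10 each. Without the array labelled 0 Gy replicate 5, 20 platelet and 16 erythroid genes rose over all genes. Both lists were called by camera with adjusted p = 1.46e-07 and 2.22e-07, and with an estimated correlation adjusted p = 0.371 and 0.411.

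Some members of the lists of inflammation and stress rose at 8 Gy. Of 30 interferon response genes 11 rose (22 adjusted over the list alone, median 0.87). Among them were Ifit3 (2.10 ± 0.49, adjusted p = 0.0202), Oas2, which senses double-stranded RNA (1.79 ± 0.40, 0.0173), Rtp4 (1.68 ± 0.36, 0.0145) and the antiviral GTPase gene Mx1 (1.44 ± 0.33, 0.0203). Of 23 NF-kB and inflammatory genes 7 rose (9 adjusted over the list alone, median 0.54). They included Ier3 (3.09 ± 0.60, adjusted p = 0.0105), Il1rn, for the interleukin 1 receptor antagonist (2.67 ± 0.51, 0.0101), and Socs3, a feedback inhibitor of cytokine signalling (2.30 ± 0.45, 0.0105). Of 19 immediate early genes 8 rose (12 and 1 lower adjusted over the list alone, median 0.78). They included the phosphatase gene Dusp1 (2.06 ± 0.53, adjusted p = 0.0280) and the AP-1 genes Junb (1.69 ± 0.33, 0.0107) and Jun (1.61 ± 0.39, 0.0233). Of 20 NRF2 and oxidative stress genes 7 rose (12 adjusted over the list alone, median 0.83). They included the heme oxygenase gene Hmox1 (1.47 ± 0.30, adjusted p = 0.0118) and the ferritin gene Ftl1 (1.21 ± 0.31, 0.0293). Without the array labelled 0 Gy replicate 5, 20 interferon response, 10 NF-kB, 12 immediate early and 11 NRF2 genes rose over all genes. Camera gave adjusted p = 2.08e-08, 0.0113, 5.13e-04 and 2.79e-04 for the 4 lists in this order, and with an estimated correlation adjusted p = 0.352, 0.417, 0.352 and 0.301. In all, camera called 15 of 24 lists at 8 Gy and 11 at 2 Gy with the preset correlation, and 0 in limma with an estimated one.

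**Figure D1:**
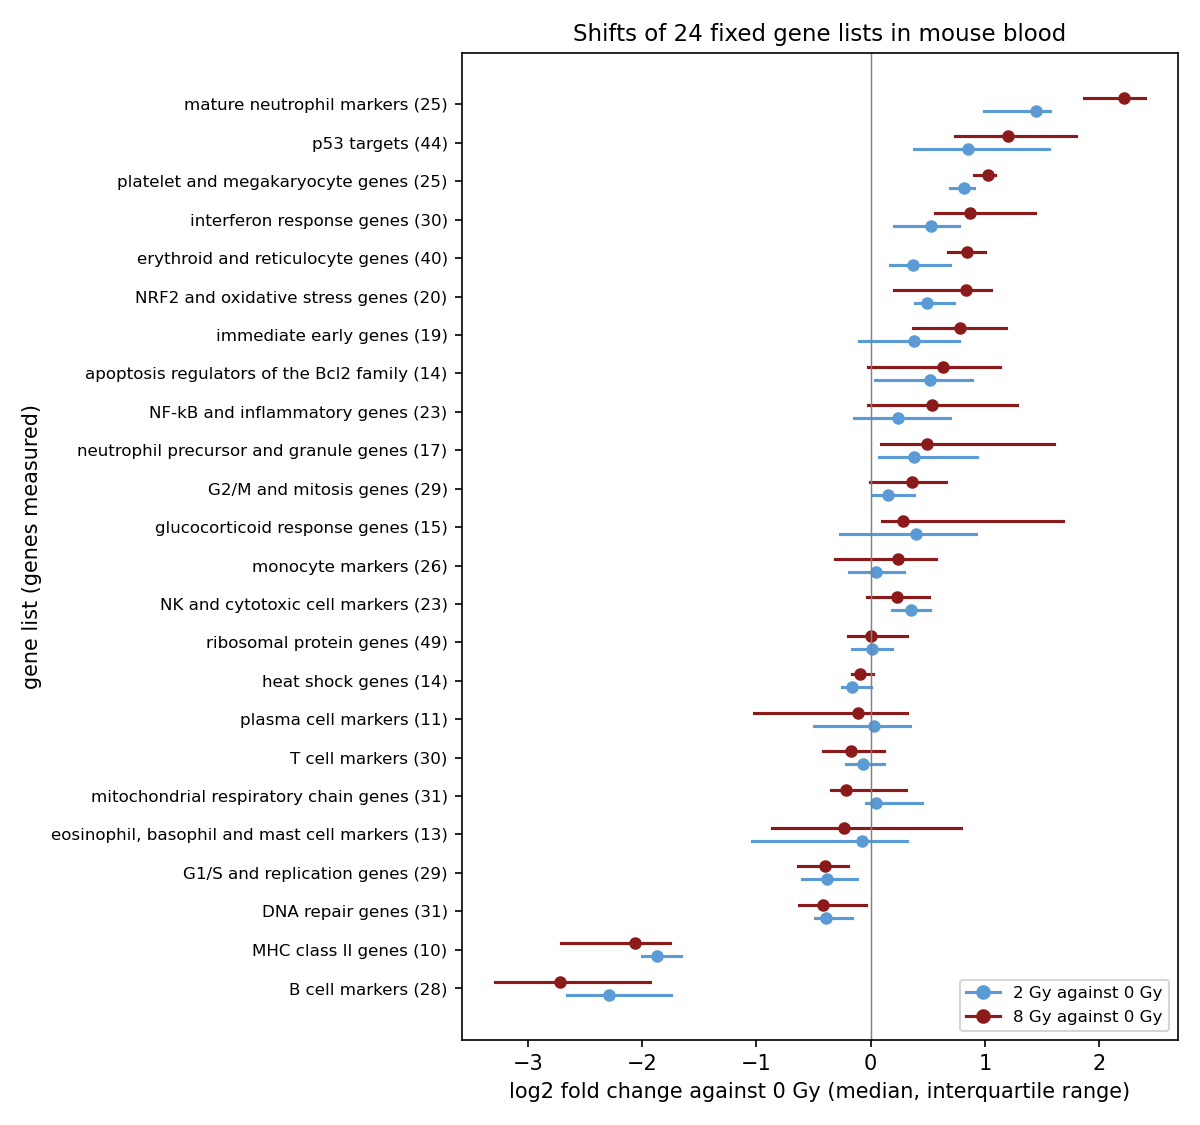
Points are medians and lines are interquartile ranges of the log2 fold change against 0 Gy (x axis) over the measured genes of each of 24 lists (y axis), in blue for 2 Gy and in red for 8 Gy. At 8 Gy the medians run from -2.72 for B cell markers to 2.22 for mature neutrophil markers, and that of monocyte markers, 0.24, was -0.33 with normexp.

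The comparison of 2 Gy with 0 Gy asks whether a lower dose leaves a mark in blood. Psrc1 rose by 4.05 ± 0.70 on the log2 scale (5 against 7 arrays, adjusted p = 0.0418, chromosome 3 from 108206316 to 108206375). Dglucy, also on the p53 list, rose by 1.88 ± 0.32 (adjusted p = 0.0418). 9230114K14Rik rose by 2.96 ± 0.45 (adjusted p = 0.0308) and was well above background on 1 of 7 arrays at 0 Gy and 5 of 5 at 2 Gy. Inka2, for a kinase inhibitor, rose by 2.59 ± 0.40 (adjusted p = 0.0308) and was well above background on 2 of 7 and 5 of 5. These genes lay above the other 0 Gy arrays, the one labelled replicate 5 aside, in 5 of 5 arrays at 2 Gy and 6 of 6 at 8 Gy. Ppm1e, for a protein phosphatase, was at least 1.54-fold lower (adjusted p = 0.0418, well above background on 6 of 7 arrays at 0 Gy and 0 of 5 at 2 Gy). Zfp94, for a zinc finger protein, was at least 1.33-fold lower (adjusted p = 0.0308, 7 of 7 and 0 of 5). D130051D11Rik was well above background on 5 of 7 and 0 of 5 arrays and its bound gave no fold (adjusted p = 0.0308). With normexp its log2 fold change was 0.09.

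In all 7 genes passed at 2 Gy, 4 higher and 3 lower, while 2706 had an unadjusted p under 0.05, and 663 were expected by chance. Without the array labelled 0 Gy replicate 5 the count was 927, 547 higher and 380 lower, 7 of the 7 among them. The count was 0 in limma without any 1 of 0 Gy replicates 1, 2, 3, 4, 6 and 7, 2 Gy replicates 1, 2, 4 and 5 and 8 Gy replicate 3, with between 1676 and 2820 genes at an unadjusted p under 0.05. It was 3 without 8 Gy replicate 5 or 6, 4 without 8 Gy replicate 4, 158 without 8 Gy replicate 1 and 212 without 2 Gy replicate 3. It was 0 with the slide or scan day as a block (1787 and 1842 genes at an unadjusted p under 0.05), in RiboPure arrays alone (1602), without a filter (5633) and with brightness as a covariate (835).

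The lists called at 2 Gy had the sign they had at 8 Gy. Of 44 p53 targets, 2 rose and 42 did not pass over all genes (27 rose and 1 fell adjusted over the list alone), with a median of 0.85. Cdkn1a had a log2 fold change of 2.66 ± 0.56 (adjusted p = 0.0625). Of 28 B cell markers 0 passed in limma over all genes and 25 fell adjusted over the list alone (median -2.29), and of 10 MHC class II genes 0 and 10 (median -1.87). Of 25 neutrophil markers 0 and 14 rose (median 1.45), and platelet genes had a median of 0.82 with 0 of 25 past either adjustment. Without the array labelled 0 Gy replicate 5, which was singled out for its p53 score, more members passed over all genes. Then 25 p53 targets rose, 24 B cell markers and 7 MHC class II genes fell, and 13 neutrophil markers and 4 platelet genes rose. By camera these lists had adjusted p = 1.26e-13, 2.84e-22, 1.43e-09, 9.10e-08 and 2.10e-07 in this order, and with an estimated correlation adjusted p = 0.281, 0.281, 0.281, 0.457 and 0.457. Camera also called DNA repair (median -0.39, adjusted p = 2.89e-05), replication (-0.38, 9.47e-05), interferon response (0.53, 2.49e-04), NRF2 (0.49, 2.39e-04), erythroid (0.37, 8.84e-04) and Bcl2 family genes (0.52, 0.0293), with adjusted p = 0.358, 0.451, 0.620, 0.281, 0.691 and 0.457 with an estimated correlation.

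The comparison of 8 Gy with 2 Gy asks whether the doses can be told from each other. No single gene passed: limma called 0 of 13260, with a lowest adjusted p of 0.927 and 415 genes at an unadjusted p under 0.05, and 0 (541) without the array labelled 0 Gy replicate 5. Camera at the preset correlation called neutrophil markers (median 0.89, adjusted p = 4.01e-08), interferon response genes (0.41, 1.00e-06) and p53 targets (0.37, 2.24e-04) higher at 8 Gy. It called B cell markers lower (-0.41, 0.00218), and of the other lists 4 higher and 3 lower. With an estimated correlation 0 of these 11 lists were called, and the named ones had adjusted p = 0.675, 0.675, 0.675 and 0.767. These medians had the opposite sign within the slide that held both doses. That slide had 1 array at 2 Gy, replicate 4, the dimmest of the series. It had the highest p53 and neutrophil scores and the lowest B cell score of its dose. The same slide held 8 Gy replicate 1, with the lowest p53 and neutrophil scores and the highest B cell score at 8 Gy. The opposite signs therefore cannot be parted from these arrays. The 1585 genes called at 8 Gy had the same sign at 2 Gy in 1585 cases and a larger size at 8 Gy in 1494, with a median ratio of 2 Gy to 8 Gy of 0.69. They were chosen for their size at 8 Gy and share the 0 Gy arrays.

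Scores gave 1 value per mouse for a list. The p53 score was 0.00 ± 0.50 at 0 Gy (n = 7), 1.06 ± 0.24 at 2 Gy (n = 5) and 1.44 ± 0.18 at 8 Gy (n = 6). It differed from 0 Gy by 1.06 at 2 Gy (exact permutation p = 0.0114, adjusted 0.0379) and by 1.44 at 8 Gy (exact permutation p = 0.00175, adjusted 0.0146). Between 8 Gy and 2 Gy it differed by 0.38 (exact permutation p = 0.0195, adjusted 0.0584). In RiboPure arrays alone the differences were 0.99, 1.35 and 0.36 with exact permutation p = 0.0397, 0.00433 and 0.0381. Of these 0 passed the adjustment over 30 tests (0.119, 0.0649 and 0.119), and of the 30 tests of all 10 scores in RiboPure arrays 0 passed. The B cell score changed by -2.11 at 2 Gy (exact permutation p = 0.00379, adjusted 0.0162) and by -2.60 at 8 Gy (exact permutation p = 0.00175, adjusted 0.0146). The difference between 8 and 2 Gy was -0.49 (exact permutation p = 0.344, adjusted 0.469). The neutrophil score differed by 1.26 at 2 Gy (exact permutation p = 0.0227, adjusted 0.0620) and by 2.13 at 8 Gy (exact permutation p = 0.00175, adjusted 0.0146). The MHC class II score differed by -1.84 and -2.36 (exact permutation p = 0.00253 and 0.00291, adjusted 0.0146 for both). At 8 Gy the interferon score differed by 1.07 and the platelet score by 0.98 (exact permutation p = 0.00233 and 0.00466, adjusted 0.0146 and 0.0175). The T cell score differed by -0.12 at 2 Gy and -0.41 at 8 Gy (exact permutation p = 0.737 and 0.0583, adjusted 0.790 and 0.125). Without the array labelled 0 Gy replicate 5 the p53 differences were 1.25 and 1.62 (exact permutation p = 0.00217 for both). That array had been singled out for its p53 score. Without it every irradiated array lay above every 0 Gy array, so the choice of array set these p at the smallest value the splits can give. At 2 Gy the neutrophil (adjusted p = 0.00812), interferon (0.0417) and platelet scores (0.0417) passed without that array but not with it. The same held for the monocyte score at 8 Gy (adjusted p = 0.0417). The p53 test for 8 Gy against 2 Gy uses no 0 Gy array, so its difference and exact permutation p stayed at 0.38 and 0.0195. Its adjusted p went from 0.0584 to 0.0417 only through the other tests in the adjustment. That change is therefore no further evidence that the p53 score differs between these doses.

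**Figure D2:**
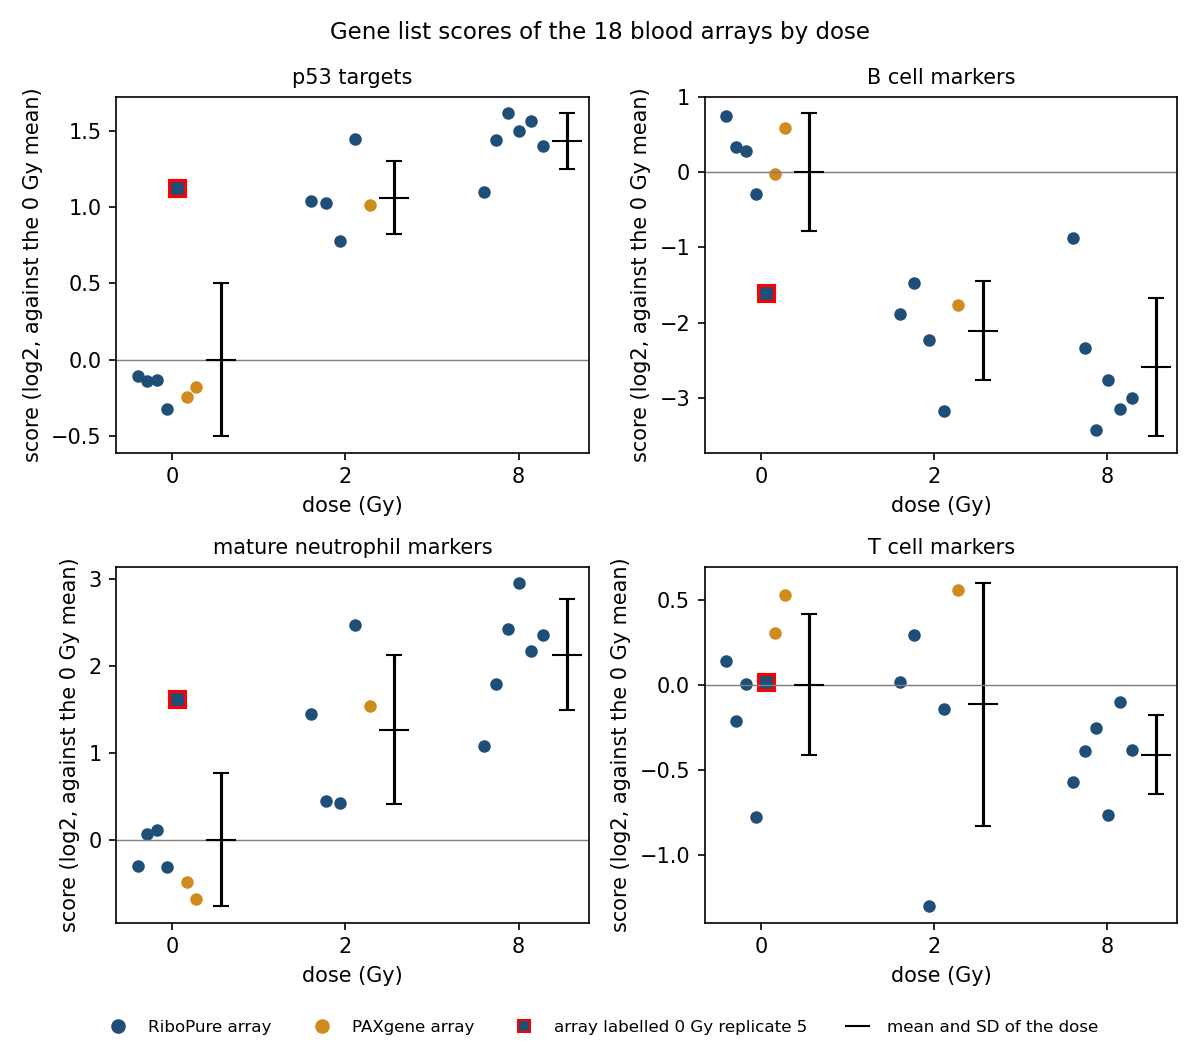
Points are the arrays at 0, 2 and 8 Gy (x axis) against the score of a list in log2 units (y axis), colours give the kit, and bars give the mean and SD of each dose (n = 7, 5 and 6). The array labelled 0 Gy replicate 5, drawn as a square, has a p53 score of 1.13, while the other 0 Gy arrays lie between -0.32 and -0.11 and those at 8 Gy between 1.10 and 1.62.

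Doses were spread unequally over the slides. Within slides that held more than 1 dose, the p53 score differed by 1.67 between 8 Gy and 0 Gy on slide 1, by 1.17, -0.35 and 1.26 between 2 Gy and 0 Gy on slides 2, 4 and 5, and by -0.08 between 8 Gy and 2 Gy on slide 7. The B cell score differed by -3.84, -2.01, -0.63, -1.74 and 1.05 on the same slides, and the neutrophil score by 2.99, 0.88, -1.19, 2.02 and -0.79. The 0 Gy array of slide 4 is the one labelled replicate 5. Slide 7 had 1 array at 2 Gy, replicate 4, the dimmest of the series. With the slide as a block the median of p53 targets was 0.81 at 2 Gy and 1.30 at 8 Gy, that of B cell markers -2.38 and -2.48, that of neutrophil markers 1.32 and 1.84, and that of MHC class II genes -2.11 and -2.09. Other medians moved more at 8 Gy: platelet genes went from 1.03 to 0.51, NF-kB genes from 0.54 to 0.31 and glucocorticoid response genes from 0.28 to 0.96. Within the PAXgene arrays, 1 at 2 Gy and 2 at 0 Gy, the scores of p53 targets, B cells and neutrophils differed by 1.23, -2.05 and 2.12.

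To ask whether the effects of the doses resemble each other, their log2 fold changes were correlated across the 13260 genes, which are not independent replicates. The correlation was 0.760 and the covariance 0.336. Both comparisons share the 0 Gy arrays, and data simulated with no effect gave a mean correlation of 0.405, with 95% of draws between -0.113 and 0.764, and a mean covariance of 0.066, with 95% of draws between -0.013 and 0.181. The observed correlation lay inside the simulated range and the observed covariance above it. With the 0 Gy arrays split between the comparisons, the correlation was 0.290 or 0.640. Without the array labelled 0 Gy replicate 5 it was 0.817, and 0.494 or 0.802 with the 0 Gy arrays split. The 4 genes called higher at 2 Gy were called higher at 8 Gy in 4 cases, where 0.31 were expected for independent calls, and 1 of the 3 lower ones was called lower, where 0.13 were expected. These expected numbers leave out the shared 0 Gy arrays, which raise the overlap with no effect at all.

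As a test of dose markers, each array was assigned to a dose from 20 genes chosen in the others. Of 18 arrays 15 were given their own dose, 6 at 0 Gy, 4 at 2 Gy and 5 at 8 Gy, and 16 were placed on their own side of irradiated or not. Over 100 orders of the labels, the real one included, the permutation p was 0.01, the smallest they can give, and the highest other order placed 14. The array labelled 0 Gy replicate 5 was assigned to 2 Gy, 2 Gy replicate 4 to 8 Gy and 8 Gy replicate 1 to 0 Gy.

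The kit was compared as a technical factor, with 3 PAXgene arrays and 15 RiboPure arrays. The PAXgene arrays alone made up slides 5 and 6 and their scan days, so the kit cannot be separated from the slide and the day. Chrna10 was higher with PAXgene by 4.94 ± 1.18 on the log2 scale (adjusted p = 0.0311), E230025N22Rik by 4.26 ± 0.83 (0.0123) and Olfr1221, an olfactory receptor gene, by 4.23 ± 0.77 (0.00783). Lalba, for a milk protein, was lower (-4.36 ± 1.12, adjusted p = 0.0429), as were 2810427C15Rik (-4.16 ± 0.31, 2.15e-06) and Steap4, a metalloreductase gene (-3.71 ± 0.91, 0.0340). Chrna10 was 3.74 and 5.49 and Lalba -3.94 and -5.04 on the PAXgene arrays of slide 5, but -0.66 and 0.46 on that of slide 6, inside the range of the RiboPure arrays. E230025N22Rik (-1.30) and Olfr1221 (-1.33) also lay inside that range on slide 6. In all 427 genes differed, 255 higher and 172 lower with PAXgene. Ribosomal protein genes were higher in 7 of 49 (24 adjusted over the list alone, median 0.66), and T cell markers in 1 of 30 (8 adjusted over the list alone, median 0.66). The camera adjusted p was 3.40e-13 and 2.09e-06 for these lists, and adjusted p = 0.912 for both with an estimated correlation. The count was 223 without 0 Gy replicate 2, 695 without 0 Gy replicate 4, 66 without 0 Gy replicate 6, 33 without 2 Gy replicate 5 and 89 with normexp.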

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

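The tests of the slides, of the array labelled 0 Gy replicate 5 and of a lower share of B cells were chosen after the results were seen, and those of brightness on the scores before. For each of 96 named genes and 10 list scores, an array was marked in its dose group when its gap to the nearest other array, as a share of the group's range, passed the 95% critical value of Dixon's test. Of 318 groups 53 were marked, where chance marks about 1 in 20, or 16 here. The array labelled 0 Gy replicate 5 accounted for 28 of them, 8 Gy replicate 1 for 12, 2 Gy replicate 4 for 5, 2 Gy replicate 3 for 3, 2 Gy replicate 5 and 8 Gy replicate 6 for 2 each and 0 Gy replicate 6 for 1.

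The array labelled 0 Gy replicate 5 was the highest of its group, with these gap shares, for Psrc1 (0.586), 9230114K14Rik (0.600), Inka2 (0.641), Dglucy (0.583), 1700007K13Rik (0.688), Tnfsf4 (0.797), Bax (0.597), Ccng1 (0.759), Aen (0.642) and the p53 score (0.853). It was also the highest for Il1r2 (0.720), Trem1 (0.643), Mmp9 (0.711), Pglyrp1 (0.720) and the neutrophil score (0.653), and for Scrg1 (0.598), Il1rn (0.655), Ier3 (0.648), Junb (0.683), Jun (0.712), Cks2 (0.579) and Cebpd (0.741). It was the lowest for Tnfrsf13c (0.645), Srpk3 (0.609), Fcmr (0.634), Cd22 (0.605), Fcer2a (0.686) and Cd79b (0.590).

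At 8 Gy, replicate 1 was the highest of its group for the B cell and MHC class II genes Tnfrsf13c (0.642), Cd22 (0.687), Fcer2a (0.715), the immunoglobulin kappa variable segment on chromosome 6 (0.659), Cd79b (0.702) and H2-Aa (0.634). It was the lowest for 9230114K14Rik (0.717), 1700007K13Rik (0.830), Trp53inp1 (0.822), Fas (0.659), Fcgr4 (0.650) and the platelet score (0.649). Its p53 score was 1.10 and its B cell score -0.88. Replicate 6 was the highest at 8 Gy for E230025N22Rik (0.825) and the lowest for Bmf (0.635).

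At 2 Gy, replicate 4 was the lowest for Cd22 (0.717), the same kappa segment (0.778), H2-Aa (0.736) and the MHC class II score (0.776) and the highest for Rtp4 (0.740). At the same dose replicate 3 was the lowest for Tnfsf4 (0.731), Bax (0.819) and Ddb2 (0.807). The PAXgene array 2 Gy replicate 5 was the lowest for Lalba (0.855) and 2810427C15Rik (0.739), and the PAXgene array 0 Gy replicate 6 was the lowest for Lalba (0.667).

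The first pattern weighed is the rise of p53 targets with the fall of B cell markers after 8 Gy, for which dimmer irradiated arrays and the slides could account. With log2 brightness as a covariate the p53 score difference went from 1.38 ± 0.21 to 1.19 ± 0.24 (95% interval 0.68 to 1.70) and that of the B cell score from -2.48 ± 0.48 to -2.02 ± 0.52 (-3.14 to -0.89), which argues against brightness as the whole cause. With the slide as a block they were 1.23 ± 0.37 (0.38 to 2.08) and -2.37 ± 0.86 (-4.36 to -0.38), which argues against the slides as the whole cause. The calls of single genes were not kept, since limma called 0 (1854 and 1130 at an unadjusted p under 0.05): the 1585 genes had the same sign in both settings, but their median size fell from 1.13 to 0.87 in each and the median standard error grew from 0.31 to 0.34 with brightness and 0.49 with the slide. An effect of the dose stays open as a hypothesis, found and tested on the same arrays, and the slide's part in single genes stays open too.

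The second pattern is the array labelled 0 Gy replicate 5, with a p53 score of 1.13, a B cell score of -1.60 and a neutrophil score of 1.62. Each array was placed on an axis from the 0 Gy mean (0) to the 8 Gy mean (1) over 13179 genes outside the p53 and B cell lists. Both means left out the array being placed and the 0 Gy mean always left out replicate 5, so the places of a group need not average 0 or 1. The array labelled 0 Gy replicate 5 lay at 0.74, against 0.09 to 0.34 for the other 0 Gy arrays, as an irradiated sample under a 0 Gy label would. However, 2 Gy replicate 3 lay at 0.15, inside the range of the other 0 Gy arrays. A swap with an irradiated array of the series would need a partner with a p53 score in the range of the other 0 Gy arrays, and 0 had one. The other 2 arrays of its scan day deviated from the rest of their dose by -0.20 on average, against an excess of 1.32 for this array. They were 2 Gy replicate 3 (-0.35), which stood apart from its group, and 8 Gy replicate 6 (-0.04). They gave no sign of a rise on that day, but both were irradiated, so they cannot exclude one in a 0 Gy array. A single wrong label, a swap with a sample outside the series and a mouse that differed for another reason stay open.

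The third pattern is the rise of neutrophil markers after 8 Gy without one of T cell markers. A lower share of B cells alone would raise both alike. The neutrophil score minus the T cell score changed by 2.54 without a kit term (pooled SD 0.83) and by 2.23 ± 0.45 with one, which argues against it. With brightness as a further covariate the change went from 2.23 ± 0.45 to 1.97 ± 0.53 (95% interval 0.83 to 3.12), which argues against brightness as the whole cause. More neutrophils in blood, more of these transcripts per neutrophil and fewer T cells along with B cells may each contribute and stay open.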

How the results depend on the processing

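The settings with brightness as a covariate, with 0 Gy replicate 4 and 2 Gy replicate 3 left out, with these and the array labelled 0 Gy replicate 5 left out, and with the slide as a block without that array were chosen after seeing the data. The p53 score and the assignment of arrays were tallied over fewer settings than the counts of genes. Those settings left out the slide, scan day, replicate number and brightness as terms, so the tallies cannot be compared. Read by the unadjusted exact permutation p, the p53 score kept its direction and stayed under 0.05 for 2 Gy and for 8 Gy against 0 Gy in 26 of 26 settings each. The number of arrays assigned to their dose stayed within 1.5 times its main value of 15 in 10 of 10. Adjusted over the 30 tests, both p53 differences lost the threshold in RiboPure arrays (0.119 and 0.0649). For 8 Gy against 2 Gy, whose adjusted p of 0.0584 did not pass in the main setting either, the unadjusted p stayed under 0.05 in 23 of 26. The difference was 0.13 with normexp and 0.30 with probes well above background on all arrays, and ranged from 0.30 to 0.47 with each array left out. In both settings, and without 2 Gy replicate 3, its unadjusted exact permutation p was above 0.05 (0.621, 0.0628 and 0.0524). The count of genes for 8 Gy against 2 Gy was 0 in limma in 41 of 41 settings, with 415 at an unadjusted p under 0.05 in the main one. Signal over background limits the dimmer genes: the irradiated arrays had fewer probes well above background, and folds of such probes are bounds or depend on the background correction. Where a cause is not given, the cause was not tested.

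The count of 7 for 2 Gy against 0 Gy stayed within 1.5 times in 8 of 41 settings. It was 0 at an adjusted p under 0.01, without a filter, in RiboPure arrays (fewer arrays), with the slide as a fixed block, with the scan day as a block and with brightness as a covariate. It was 2 with only the 2 groups compared, 3 with median scaling, 19 with every probe by itself (more tests), and 33 with probes well above background on all arrays. It was 40 with quantile normalization, 44 with the trend and robust options and 53 with normexp. It was 104 with the slide as a block without the array labelled 0 Gy replicate 5, 2398 without all 3 arrays, and from 0 to 927 with each array left out. The count of 1585 for 8 Gy against 0 Gy stayed within 1.5 times in 13 of 41. It was 0 with the slide as a fixed block, the scan day as a block or brightness as a covariate, 6 with the slide as a block without the array labelled 0 Gy replicate 5, 95 at an adjusted p under 0.01, and 283 in RiboPure arrays. It was 460 with median scaling, 564 without a filter, 596 with the slide as a random block (within-slide correlation 0.149), 783 with only the 2 groups compared, 1047 with a fold of at least 2, 3478 without all 3 arrays, and from 268 to 3022 with each array left out. The kit count of 427 was 81 at an adjusted p under 0.01, 89 with normexp and from 33 to 695 with each array left out. The median of all genes at 2 Gy was 0.06, and -0.06 with median scaling and -0.04 with quantile normalization; at 8 Gy it was 0.08, 0.02 and -0.02.

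With the replicate number as a block, 67 genes passed for 2 Gy and 238 for 8 Gy against 0 Gy. The numbers of the labels did not pair the arrays: arrays with the same number had correlations from -0.499 to 0.310 once the dose was removed.

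With an estimated correlation, camera called 0 lists at 2 Gy and at 8 Gy in place of 11 and 15, and the calls of B cell markers (-2.29 and -2.72) and p53 targets (0.85 and 1.20) were lost with unchanged medians. Over all settings, that of the estimated correlation included, list shifts held in 2610 cases and were weaker in 128, stronger in 121, moved in 36 and reversed in 33. Named genes held in 7945 and were weaker in 949, stronger in 258, moved in 202 and reversed in 8. Weaker and stronger mean a call lost or gained at the threshold, whatever the size of the value. The correlation of the effects of both doses was 0.290 with odd 0 Gy numbers given to 2 Gy.

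The reversed values are those that changed sign and were called in the main setting or the alternative. Changes of sign with no call in either were counted above as held or moved, not as reversed. With the slide as a block such uncalled changes included G2/M genes (0.15 to -0.21) and monocyte markers (0.05 to -0.11) at 2 Gy. For 8 Gy against 2 Gy the uncalled changes included NK markers (-0.16 to 0.28) and platelet genes (0.25 to -0.04). The reversed values were as follows. The median of ribosomal protein genes at 2 Gy was -0.27 with normexp, -0.43 with quantile normalization, -0.42 with the deposited table and -0.24 with the slide or the scan day as a block. With normexp D130051D11Rik was 0.09 at 2 Gy, at 8 Gy monocyte markers were -0.33, Zfp94 0.15 and Cd200r3 0.33, and heat shock genes were -0.22 for 8 Gy against 2 Gy. Rps29 at 8 Gy was -0.06 with quantile normalization and with the deposited table. For 8 Gy against 2 Gy, eosinophil, basophil and mast cell markers were -0.11 with probes well above background on all arrays, MHC class II genes 0.05 with the slide as a fixed block, and mitochondrial genes 0.03 without 2 Gy replicate 3 (from -0.32 to 0.03 with each array left out), 0.02 without the pair and 0.03 without all 3 arrays. With the slide as a block without the array labelled 0 Gy replicate 5, interferon response genes were 0.00, MHC class II genes 0.31, NF-kB genes -0.01 and platelet genes -0.30 for 8 Gy against 2 Gy. Within slide 4, whose 0 Gy array is the one labelled replicate 5, the values for 2 Gy against 0 Gy were -0.69 for p53 targets, -0.91 for Bcl2 family genes, -0.85 for erythroid, -0.81 for interferon response, -1.48 for neutrophil, -0.52 for NRF2 and -1.17 for platelet genes, -0.90 for Psrc1, -0.14 for 9230114K14Rik and -0.45 for Inka2. Within slide 7, the values for 8 Gy against 2 Gy were 1.16 for B cell markers, 1.59 for MHC class II, -0.03 for erythroid, -0.13 for immediate early, -0.55 for interferon response, -0.78 for mature neutrophil, -0.62 for neutrophil precursor, 0.05 for mitochondrial and -0.18 for NF-kB genes, and -0.12 for p53 targets. Of the medians of B cell markers and p53 targets against 0 Gy, those that moved and kept their sign were B cell markers (-4.41) and p53 targets (1.76) for 8 Gy against 0 Gy within slide 1, and B cell markers (-0.60) for 2 Gy against 0 Gy within slide 4.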

Other observations

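The tests by splits of the arrays in this part were planned before their results were seen, and the look at where a pair of arrays fell in them was chosen after. Among cell types not described so far, 2 of 26 monocyte markers rose at 8 Gy (2 adjusted over the list alone), the IgG receptor genes Fcgr4 (1.62 ± 0.36 on the log2 scale, adjusted p = 0.0180) and Fcgr3 (1.40 ± 0.34, 0.0245). The median of the list was 0.24 (camera adjusted p = 0.552), and -0.33 with normexp. Of 13 eosinophil, basophil and mast cell markers 2 fell (2 adjusted over the list alone, median -0.23, camera adjusted p = 0.284). They were Il5ra, the interleukin 5 receptor chain of eosinophils (-2.54 ± 0.65, adjusted p = 0.0283), and Cd200r3, which was well above background on 5 of 7 arrays at 0 Gy and 0 of 6 at 8 Gy and was at least 1.04-fold lower (adjusted p = 0.0215), with a log2 fold change of 0.33 under normexp. Of 23 NK and cytotoxic cell markers and 11 plasma cell markers, limma called 0 over all genes. Adjusted over the list alone, 0 NK markers passed and 2 plasma cell markers rose and 1 fell, with list medians of 0.23 and -0.11. Without the array labelled 0 Gy replicate 5, 4 monocyte and 4 NK markers rose over all genes. Of the eosinophil, basophil and mast cell markers 2 then rose and 2 fell, and of the plasma cell markers 2 rose and 1 fell.

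Of 29 G2/M and mitosis genes Cks2, a partner of cyclin-dependent kinases, rose at 8 Gy (1.17 ± 0.31, adjusted p = 0.0305; 1 adjusted over the list alone, median 0.36, camera adjusted p = 0.145). Of 15 glucocorticoid response genes 4 rose (5 adjusted over the list alone): Il1r2, Dusp1, the transcription factor gene Cebpd (2.00 ± 0.47, adjusted p = 0.0216) and the mTOR inhibitor gene Ddit4 (1.04 ± 0.30, 0.0397), which kept its call in 10 of 34 settings. The list's median was 0.28 and its camera adjusted p was 0.0619. Of 14 heat shock genes 0 passed over all genes or the list alone (median -0.09). Of 49 ribosomal protein genes 2 rose over all genes and 0 adjusted over the list alone: Rpl38 (0.82 ± 0.23, adjusted p = 0.0380) and Rps29 (0.77 ± 0.25, 0.0495), which had -0.06 with quantile normalization and with the deposited table. The median of that list was 0.00, its mean 0.07 and its test pointed down (camera adjusted p = 0.899). Of 31 mitochondrial respiratory chain genes 2 rose, Cox6c (0.88 ± 0.24, adjusted p = 0.0322) and Atp5h (0.66 ± 0.20, 0.0465), 6 and 1 lower adjusted over the list alone, while the median was -0.22 and the mean -0.04 (camera adjusted p = 0.465). Of 34 settings Rpl38 kept its call in 12, Rps29 in 7, Cox6c in 15 and Atp5h in 8. Without the array labelled 0 Gy replicate 5, 6 ribosomal protein, 7 mitochondrial, 3 G2/M and 5 glucocorticoid response genes rose over all genes. Of the heat shock genes 1 then rose and 1 fell.

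Random splits of the arrays were fitted in the same way, 100 for each comparison with the real split included. For 8 Gy against 0 Gy, 1 split reached 1585 genes, the real one, and the highest other gave 5, which argues against chance. A share of 1 in 100 is the smallest these splits can give, so they cannot fully exclude it. The splits did not keep the slides together, and with the slide or the scan day as a block the real count was 0. For 2 Gy against 0 Gy, 4 splits reached the real 7, and the other 3 gave 528, 1946 and 2005 genes, many times the real count, which points to a structure of the samples. The splits with 1946 and 2005 put 0 Gy replicate 4 and 2 Gy replicate 3 together on the 2 Gy side, and the one with 528 put them on opposite sides. Of 12 splits with that pair together on the 2 Gy side, the other 10 gave 0 or 1 gene, so the pair alone does not account for the high counts. Few of the 100 splits reached 7 genes, but 3 random ones gave far more, so chance is not excluded for this count. The splits also ignored the slides, and the real count was 0 with the slide or the scan day as a block. For 8 Gy against 2 Gy, 100 of 100 splits reached the real 0 and the highest other gave 164. For the kits, 4 splits reached the real 427, and the other 3 gave 578, 961 and 1483 genes, each with that same pair in the PAXgene group, which again points to a structure of the samples. Since 3 random splits exceeded the kit count, chance is not excluded for it either. The PAXgene arrays alone made up slides 5 and 6 and their scan days, so these splits also do not part the kit from the slide and the day.

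The scanner software gave 2 Gy replicate 4 and 8 Gy replicate 2 a gridding status of 2. The highest correlation between any pair of arrays was 0.983, and 0 pairs were identical.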
